A study of Mus musculus with 6 samples.

How the data were processed

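RNA sequencing libraries of sorted visceral adipose macrophages were compared in 3 groups of 2 libraries each: ethanol vehicle (EtOH), estradiol (E2) and 4-hydroxyestrone (4-OHE1), the last named E1170 in some of the authors' column names. Per the labels, mRNA libraries were made with a KAPA mRNA HyperPrep kit and sequenced on a HiSeq2500. The submitters' processing notes list the mouse build mm9, STAR, HOMER, DESeq2 and edgeR without versions. Per the file headers, the authors counted reads over the exons of RefSeq genes with HOMER and kept 1 isoform per gene.

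The deposited RPKM table gives rpkm, reads normalised to kilobases of exon and to the total tags of each library, for all 6 libraries. The authors' 2 pairwise edgeR tables, E2 against EtOH and 4-OHE1 against EtOH, hold signal columns, which are exon read counts scaled to a common total within each table. The deposited edgeR tables also give log2 fold changes, each estrogen over EtOH, with p-values and adjusted p-values. The authors' shorter sheets of genes at least 2-fold lower repeat genes of the full sheets and were not used here. Each of the 119614 signal values above 0 lay within 0.05 of a whole read after division by 1 factor per library, so whole reads were recovered. The 24421 genes of the tables were joined by symbol, and 266 whose transcript differed between both edgeR tables were left out of the tests on reads. Only 21370 genes had the same transcript in the RPKM table and the 4-OHE1 edgeR table. For the others, the tests on reads and on RPKM measured different transcripts of the gene.

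The files hold no raw counts, so the main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(RPKM + 1) for genes with a mean RPKM of at least 1 over the 6 libraries, with all 6 libraries in 1 fit of group means. Tests were two-sided, with Benjamini-Hochberg adjustment over 10950 genes and a threshold of 0.05. The edgeR quasi-likelihood test planned for raw counts was run as an alternative on the recovered reads (edgeR 4.0.16), as was DESeq2 1.42.0. The comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The share of reads in exons then proved to differ between groups, and a second scaling was added: RPKM rescaled to each library's exon reads at the mean exon share of EtOH. Genes are called only where both scalings pass in the same direction.

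The depth was 4515276 to 35293924 exon reads per library, with 16042.5 genes having a read on average in EtOH, 14667 in E2 and 13055.5 in 4-OHE1. Over 1134 genes with a mean RPKM of at least 50, the median coefficient of variation between replicates was 2.21% in EtOH, 5.56% in E2 and 6.16% in 4-OHE1. For genes with 20 to 1000 reads, the variance between replicates exceeded counting noise by a factor of 3.10 in EtOH, 4.14 in E2 and 9.62 in 4-OHE1. The tests were tested on simulated data of the same depth, noise and group sizes. There limma recovered 40 of 100 genes changed 2-fold and 75 of 99 changed 4-fold in E2, with 5 false calls among 11150 genes. In 4-OHE1 it recovered 39 of 100 and 67 of 99, with 38 false calls among 11167. Beside the 39 and 67 genes recovered, the 38 false calls were a larger share of all calls than the adjusted p threshold allows. Limma therefore did not hold its threshold in the simulated 4-OHE1 data. On the same simulated data edgeR recovered 47 and 87 of 100 in E2 and 45 and 83 of 100 in 4-OHE1, with 0 and 6 false calls. In the real libraries the factor rose with the number of reads, to 243 in E2 for genes with at least 10000. Calls below also had to pass both scalings, so the simulated rates do not describe them directly. The share of false calls among them was not tested.

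Gene lists, 35 in number, were tested with camera of limma at its preset correlation of 0.01 where at least 3 genes were tested, which held for 30. They covered NRF2 antioxidant targets, HSF1 heat shock chaperones, mitochondrial chaperones and proteases, the integrated stress response, NF-kB and inflammatory cytokines, interferon-stimulated genes, lipid-associated, resident perivascular, core macrophage, alternative activation and monocyte genes, MHC class II, oxidative phosphorylation, the TCA cycle with fatty acid oxidation, glycolysis with hypoxia, cholesterol synthesis, LXR targets with lipogenesis, lysosome, cell cycle, estrogen receptors with estrogen-responsive genes, glucocorticoid-responsive genes, immediate early genes, and markers of 13 other cell types or tissues. The series title names mitohormesis and tolerance, which the first lists address. The adjusted p printed for a list is the larger of both scalings. Each list's call was repeated with a correlation estimated per list and with fry, both with the authors' scaling alone.

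Named genes are, for each comparison, the 12 with the largest log2 change in each direction among those past the threshold with a mean CPM (reads scaled to library size) of at least 5 and no overlap between the groups' libraries, up to 4 members of each list with the smallest p, and a fixed set including Esr1, Nqo1, Hmox1, Tnf, Trem2 and Adgre1. The effects of both estrogens were compared by their correlation and covariance across genes and by the number of shared calls. The reference was 100 simulated draws with no effect, the same shared EtOH libraries and an equal spread in every group. Alternatives changed the normalization, pseudocount, filters, libraries in the fit, replicate block, test and single libraries left out. Added after the data were seen were the exon scaling, edgeR with TMM on recovered reads, reads thinned to the smallest library, reads divided by the replicate noise factor, and the omission of features under 200 bases. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.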

Results

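RNA was sequenced from macrophages of visceral white adipose tissue, the fat around the abdominal organs, of male C57BL/6N mice fed a diet with 60 kcal% fat. Mice aged 12 weeks received subcutaneous injections every 6 days for 30 days of ethanol vehicle (EtOH), of estradiol (E2) at 10 mg/kg, or of 4-hydroxyestrone (4-OHE1) at 10 mg/kg. Live cells positive for F4/80 and CD11b, surface proteins of macrophages, were sorted from the digested tissue. There were 6 libraries, 2 for each group, and the labels do not say whether the libraries of a group come from separate animals. All p-values below therefore measure only the spread between these libraries, which may be technical. Replicates 1 and 2 held 18697456 and 35293924 reads in exons in EtOH, 5349386 and 5606659 in E2, and 5764342 and 4515276 in 4-OHE1.

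The share of reads that lay in exons differed between the groups: 84.8% ± 0.366 (SD, n = 2) in EtOH, 74.1% ± 2.41 in E2 and 61.7% ± 1.19 in 4-OHE1. Malat1, a long RNA kept in the nucleus, stood at 198.8 ± 1.83 RPKM in EtOH, 433 ± 103.6 in E2 and 919 ± 93.6 in 4-OHE1. RPKM is a read count normalised to exon length and to the tags of the library. The authors divided by all tags, so the median log2 change over 10950 tested genes was -0.18 for E2 against EtOH, -0.44 for 4-OHE1 against EtOH and -0.25 for 4-OHE1 against E2. Each change was therefore also computed relative to the reads in exons, which put these medians at 0.00, -0.04 and -0.02. A gene is said below to have risen or fallen only where it passed under both scalings in the same direction. Log2 changes are those relative to exon reads, each adjusted p is the larger of both scalings, and RPKM are means as the authors give them, with SD and n = 2. Because 1 RPKM was added before the logarithm, changes of genes near or below 1 RPKM in either group are printed smaller than the ratio of their RPKM. Coordinates are those of mouse genome build mm9.

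The first comparison asked what estradiol changed against the vehicle. Saa3, an acute-phase serum amyloid gene, stood at 24.6 ± 3.94 RPKM in EtOH and 327 ± 30.0 in E2, a log2 change of 3.88 (adjusted p = 4.0e-04). Arg1, the arginase of alternatively activated macrophages, rose from 46.2 ± 3.68 to 164 ± 9.77 RPKM (log2 change 2.0, adjusted p = 7.9e-04). Fkbp5, a chaperone gene induced by glucocorticoids, rose from 11.8 ± 0.608 to 68.3 ± 7.0 RPKM (log2 change 2.62, adjusted p = 4.0e-04). Genes of lipid-associated macrophages were among those that went the other way: Spp1, which encodes osteopontin, went from 127 ± 6.85 to 22.3 ± 0.111 RPKM (log2 change -2.27, adjusted p = 4.0e-04). Trem2, a lipid receptor of these macrophages, went from 299.7 ± 11 to 116 ± 8.13 RPKM (log2 change -1.17, adjusted p = 0.00102).

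These genes lie as follows: Saa3 (NM_011315) at chromosome 7, 53967368 to 53971046, Arg1 (NM_007482) at chromosome 10, 24635013 to 24647276, and Fkbp5 (NM_010220) at chromosome 17, 28535698 to 28623094. Spp1 (NM_009263) lies at chromosome 5, 104864130 to 104870072, and Trem2 (NM_031254) at chromosome 17, 48485726 to 48491601. Reads of the serum amyloid family cannot be assigned to its members with certainty.

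Of 10950 genes, 192 rose and 238 fell in E2 under both scalings. Among them, 115 rose and 92 fell at least 2-fold, and 25 rose and 14 fell at least 4-fold. With the authors' scaling 193 genes were higher and 596 lower, and relative to exon reads 348 were higher and 238 lower, so the balance of directions turned with the scaling. The genes with the largest increases included Alox15, a lipoxygenase (log2 change 3.47), Slpi, a secreted protease inhibitor (2.98), and Thbs1, which encodes thrombospondin (2.93). Ddit4, an inhibitor of mTORC1 signalling, rose from 31.5 ± 2.07 to 174 ± 12.8 RPKM (log2 change 2.62), and Cxcl13, a B cell chemokine, from 8.45 ± 1.0 to 49.0 ± 8.11 (log2 change 2.59). Amica1, an adhesion molecule, rose by 2.53 on the log2 scale, with the caution that its coordinates overlap those of Gm10684. The largest falls included Gpnmb, a lysosomal glycoprotein, from 225 ± 6.81 to 37.4 ± 1.67 RPKM (log2 change -2.37), and Cyp2s1, a cytochrome P450, from 9.42 ± 0.0651 to 0.596 ± 0.00212 (log2 change -2.63, or -3.61 with 0.1 RPKM added in place of 1, where it did not pass).

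Of the 20 tested lipid-associated macrophage genes, 1 rose, 13 fell and 6 did not pass (adjusted over the list alone, 1 rose and 16 fell). Lipid-associated macrophage genes passed as a list, lower (median log2 change -1.04, camera adjusted p = 2.7e-11, adjusted p = 0.0942 with an estimated correlation). Members that fell included Lpl, lipoprotein lipase, at a log2 change of -1.34, and Ctsl, a lysosomal protease, at -1.39. Of the 27 lysosome genes, 0 rose, 7 fell and 20 did not pass (adjusted over the list alone, 0 rose and 10 fell). Lysosome genes passed as a list, lower (median log2 change -0.14, camera adjusted p = 1.3e-05, adjusted p = 0.276 with an estimated correlation). Ctsd, a lysosomal aspartic protease, fell from 1574 ± 21.2 to 747 ± 66.9 RPKM (log2 change -0.88), and Atp6v1b2, a subunit of the proton pump, had a log2 change of -0.69. Of the 22 cholesterol synthesis genes, 0 rose, 7 fell and 15 did not pass (adjusted over the list alone, 0 rose and 11 fell). Cholesterol synthesis genes passed as a list, lower (median log2 change -0.70, camera adjusted p = 7.5e-08, adjusted p = 0.0974 with an estimated correlation). Falling members included Cyp51 at -1.58, Sqle at -1.39 and Fdps at -1.23, all enzymes of the pathway.

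Of the 29 cell cycle genes, 0 rose, 10 fell and 19 did not pass (adjusted over the list alone, 0 rose and 22 fell). Cell cycle genes passed as a list, lower (median log2 change -0.77, camera adjusted p = 1.4e-12, adjusted p = 0.0674 with an estimated correlation). Top2a, the topoisomerase of dividing cells, went from 13.9 ± 1.37 to 5.20 ± 0.0827 RPKM (log2 change -1.10), Ccnb2, a mitotic cyclin, changed by -1.0, and Mcm6, of the replication helicase, by -0.78. Of the 14 glucocorticoid-responsive genes, 8 rose, 0 fell and 6 did not pass (adjusted over the list alone, 10 rose and 0 fell). Glucocorticoid-responsive genes passed as a list, higher (median log2 change 0.73, camera adjusted p = 6.5e-13, adjusted p = 0.0674 with an estimated correlation). Besides Fkbp5 and Ddit4, Klf9, a transcription factor, rose by 1.35 and Cd163, the haemoglobin scavenger receptor, by 0.89 on the log2 scale. Adipocyte markers stood higher beside these groups: of 10 tested, 4 rose, 0 fell and 6 did not pass (adjusted over the list alone, 7 rose and 0 fell). Adipocyte markers passed as a list (median log2 change 0.85, camera adjusted p = 4.2e-07, adjusted p = 0.0674 with an estimated correlation). Cfd, which encodes adipsin, rose from 4.59 ± 0.279 to 27.5 ± 0.0332 RPKM (log2 change 2.54), and Car3, a carbonic anhydrase of fat cells, from 32.0 ± 2.09 to 91.7 ± 1.62 (log2 change 1.69). Scd1, a fatty acid desaturase that fat cells also express, rose by 1.53.

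Of the 17 alternative activation genes, 6 rose, 2 fell and 9 did not pass (adjusted over the list alone, 6 rose and 4 fell). Alternative activation genes passed as a list, higher (median log2 change 0.16, camera adjusted p = 0.0251, adjusted p = 0.227 with an estimated correlation). Members went both ways: Chil3, a chitinase-like protein gene, rose by 2.43 and Mgl2, a lectin, by 0.97, whereas Retnla, a resistin-like gene, changed by -0.27. Reads of Chil3 cannot be told with certainty from those of its near copy Chil4. Of the 14 monocyte genes, 5 rose, 0 fell and 9 did not pass (adjusted over the list alone, 6 rose and 0 fell). Monocyte genes passed as a list, higher (median log2 change 0.60, camera adjusted p = 1.0e-06, adjusted p = 0.0942 with an estimated correlation). They included Ly6c2, the monocyte surface antigen with a near copy in Ly6c1 (0.538 ± 0.439 and 4.97 ± 1.29 RPKM, log2 change 2.13, or 3.35 with 0.1 RPKM added, where it did not pass), and Fn1, fibronectin (67.0 ± 1.38 and 123 ± 12.2 RPKM, log2 change 1.06). Markers of peritoneal macrophages rose beside them: of 7 tested, 4 rose, 0 fell and 3 did not pass (adjusted over the list alone, 4 rose and 0 fell). Peritoneal macrophage markers passed as a list (median log2 change 1.58, camera adjusted p = 4.2e-07, adjusted p = 0.117 with an estimated correlation). Prg4, which encodes lubricin, rose from 3.84 ± 0.444 to 25.8 ± 2.77 RPKM (log2 change 2.66), Serpinb2 by 2.86, and Selp, P-selectin, by 1.58 (2.66 with 0.1 RPKM added, where it did not pass).

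Among metabolic lists, 2 also passed as lower. Of the 27 genes of the TCA cycle and fatty acid oxidation, 0 passed limma in either direction, also adjusted over the list alone, with 6 lower at an unadjusted p under 0.05 and 1 lower by edgeR. As a list they passed as lower (median log2 change -0.13, camera adjusted p = 0.0257, adjusted p = 0.245 with an estimated correlation). Of the 21 glycolysis and hypoxia genes, 1 rose, 3 fell and 17 did not pass (adjusted over the list alone, 1 rose and 4 fell). Glycolysis and hypoxia genes passed as a list, lower (median log2 change -0.31, camera adjusted p = 0.0395, adjusted p = 0.245 with an estimated correlation). Tpi1, a glycolytic enzyme, changed by -0.52 and Vegfa, a growth factor for blood vessels, rose by 1.78. Of the 12 adipose stromal cell markers, 0 rose, 4 fell and 8 did not pass (adjusted over the list alone, 0 rose and 6 fell). Stromal cell markers passed as a list, lower (median log2 change -0.40, camera adjusted p = 0.0149, adjusted p = 0.327 with an estimated correlation), with Col1a1, a collagen, at 26.4 ± 0.245 and 8.44 ± 1.12 RPKM (log2 change -1.37). Of 3 tested epididymis and testis markers 2 rose, 0 fell and 1 did not pass (adjusted over the list alone, 3 rose and 0 fell), and the list passed as higher (median log2 change 1.87, camera adjusted p = 0.00142, adjusted p = 0.213 with an estimated correlation). One was Prm1, a sperm protamine, at 0.118 ± 0.00566 RPKM in EtOH and 4.48 ± 1.26 in E2 (log2 change 2.43, from a level near 0). Adgre1, which encodes the sorting antigen F4/80, went from 303 ± 3.08 to 172 ± 8.13 RPKM (log2 change -0.62).

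Inflammatory and stress genes did not pass as lists. Of the 23 NF-kB and inflammatory cytokine genes, 3 rose, 3 fell and 17 did not pass (adjusted over the list alone, 5 rose and 3 fell), with a median log2 change of -0.01, a mean of 0.23, an upward test and a camera adjusted p of 0.328. Socs3, a feedback inhibitor of cytokine signalling, went from 106 ± 1.82 to 30.1 ± 4.82 RPKM (log2 change -1.60). Tnf stood at 32.5 ± 3.33 and 45.1 ± 3.44 RPKM, with a log2 change of 0.65 that did not pass (adjusted p = 0.0749). Of the 20 NRF2 antioxidant targets, 0 rose, 2 fell and 18 did not pass (adjusted over the list alone, 1 rose and 4 fell), and the list passed with the authors' scaling alone (adjusted p = 0.0351, and 0.164 relative to exon reads). Of the 19 HSF1 heat shock chaperones, 18 mitochondrial chaperones and proteases, 29 interferon-stimulated genes and 50 oxidative phosphorylation genes, 0 passed limma in either direction, also adjusted over the list alone. At an unadjusted p under 0.05, 3, 0, 6 and 0 of them did, and edgeR called 0, 0, 2 and 0. The other lists that did not pass under both scalings were the integrated stress response (1 rose, 1 fell of 19), resident perivascular macrophages (2 rose, 1 fell of 19), MHC class II (0 rose, 1 fell of 13), LXR targets and lipogenesis (1 rose, 4 fell of 15), estrogen receptors and estrogen-responsive genes (0 rose, 2 fell of 12), immediate early genes (3 rose, 2 fell of 19) and core macrophage genes (0 rose, 3 fell of 16). Adjusted over the list alone, these 7 lists had 2 and 2, 5 and 4, 3 and 1, 2 and 5, 2 and 2, 4 and 3, and 2 and 4 genes higher and lower. In edgeR they had 3 and 1, 6 and 3, 5 and 1, 1 and 4, 3 and 2, 5 and 3, and 3 and 3. Relative to exon reads alone, MHC class II (median 0.18, camera adjusted p = 0.00754) and immediate early genes (0.17, 0.0373) passed as higher and LXR targets (-0.20, 0.0337) as lower. With the authors' scaling alone, oxidative phosphorylation (adjusted p = 0.0190) and core macrophage genes (0.0351) passed as lower.

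With an estimated correlation between genes, camera passed 0 of 30 lists in this comparison at an adjusted p under 0.05 and 7 at an unadjusted p. Fry, which tests whether a list moves on balance one way, passed 21 with the authors' scaling. The median of all genes was itself lower under that scaling, so passes of fry do not add to the list calls. The count of genes that passed both scalings went from 430 to 47 and 46 without EtOH replicate 1 or 2, to 83 and 84 without E2 replicate 1 or 2, and to 1031 and 1037 without 4-OHE1 replicate 1 or 2. Of the genes above whose printed log2 change passed in this comparison, Alox15, Amica1, Arg1, Car3, Cfd, Chil3, Ctsd, Ctsl, Cxcl13, Ddit4, Fkbp5, Gpnmb, Lpl, Mgl2, Prg4, Saa3, Scd1, Slpi, Socs3, Spp1 and Trem2 kept their call under every alternative tried, and the others lost it under at least 1.

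**Figure D1:**
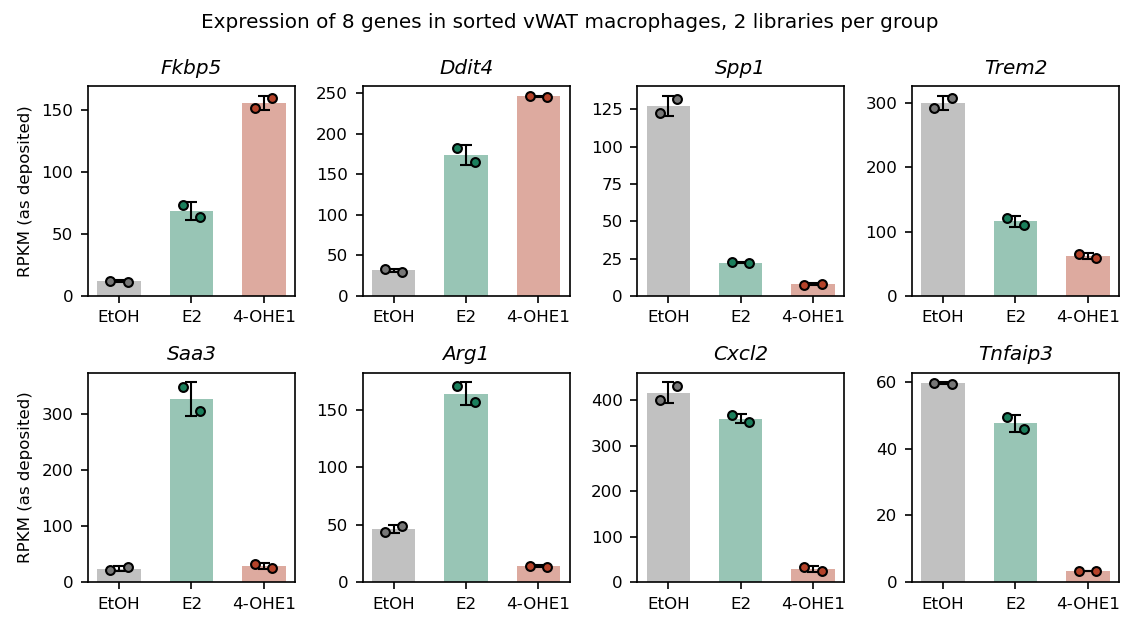
Bars show the mean RPKM (from 0) of 8 genes in EtOH, E2 and 4-OHE1, error bars the SD and points the 2 libraries of each group. Fkbp5 and Ddit4 are highest in 4-OHE1, Spp1 and Trem2 highest in EtOH, Saa3 and Arg1 highest in E2, and Cxcl2 and Tnfaip3 lowest in 4-OHE1.

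The second comparison asked what 4-hydroxyestrone changed against the vehicle. Cxcl2, a neutrophil chemokine, went from 416 ± 22.8 to 29.9 ± 6.24 RPKM (log2 change -3.32, adjusted p = 3.2e-05). Tnfaip3, which encodes the NF-kB inhibitor A20, went from 59.5 ± 0.214 to 3.50 ± 0.0148 RPKM (log2 change -3.38, adjusted p = 2.0e-05). Spp1 went from 127 ± 6.85 to 7.91 ± 0.426 RPKM (log2 change -3.43, adjusted p = 2.0e-05) and Trem2 from 299.7 ± 11 to 61.7 ± 4.2 (log2 change -1.81, adjusted p = 4.0e-05). Fkbp5 rose from 11.8 ± 0.608 to 156 ± 5.52 RPKM (log2 change 4.07, adjusted p = 2.0e-05). Cxcl2 (NM_009140) lies at chromosome 5, 91332925 to 91334964, Tnfaip3 (NM_009397) at chromosome 10, 18720717 to 18735216.

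Under both scalings 629 genes rose and 1521 fell, 506 and 565 of them at least 2-fold and 65 and 132 at least 4-fold. In the simulated data limma gave more false calls for 4-OHE1 against EtOH than its adjusted p threshold allows. How many of the genes called here are false was not tested. The authors' scaling gave 629 higher and 4328 lower, and exon reads 1399 higher and 1521 lower; 18 genes were called in opposite directions. Large increases included Zbtb16, a transcription factor induced by glucocorticoids, from 1.52 ± 0.355 to 28.0 ± 0.663 RPKM (log2 change 3.98), and Amica1 with a log2 change of 4.56. Rnf169, a ubiquitin ligase, rose by 3.77 and Vcam1, a vascular adhesion molecule, from 30.9 ± 0.682 to 190.1 ± 12.3 RPKM (log2 change 3.04). Large falls included Socs3 (log2 change -3.80), Atf3, a stress-induced transcription factor (-3.83), Il1rn, the interleukin-1 receptor antagonist (-3.76), and Rnase2a, of the family that Ear2 belongs to (-3.55), whose reads may be shared with near copies.

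Of the 23 NF-kB and inflammatory cytokine genes, 1 rose, 15 fell and 7 did not pass (adjusted over the list alone, 1 rose and 18 fell). Inflammatory genes passed as a list, lower (median log2 change -1.14, camera adjusted p = 4.1e-04, adjusted p = 0.269 with an estimated correlation). Besides those above, Cxcl1, another neutrophil chemokine, went from 74.1 ± 3.37 to 3.37 ± 0.117 RPKM (log2 change -3.74), Ccl2, a monocyte chemokine, changed by -1.39 and Tnf by -0.51. Of the 19 immediate early genes, 1 rose, 12 fell and 6 did not pass (adjusted over the list alone, 1 rose and 15 fell). Immediate early genes passed as a list, lower (median log2 change -0.51, camera adjusted p = 9.0e-06, adjusted p = 0.269 with an estimated correlation). Fos, an AP-1 subunit, went from 681 ± 3.30 to 171 ± 6.75 RPKM (log2 change -1.53), Dusp1, a MAP kinase phosphatase, changed by -1.20 and Zfp36, an RNA-destabilising protein, by -1.13. This list and the inflammatory list share 1 gene, Socs3. Of the 29 interferon-stimulated genes, 5 rose, 1 fell and 23 did not pass (adjusted over the list alone, 4 rose and 3 fell). Interferon-stimulated genes passed as a list, higher (median log2 change 0.34, camera adjusted p = 0.0281, adjusted p = 0.269 with an estimated correlation). The list did not pass fry (adjusted p = 0.457), and edgeR called 11 of its genes higher and 2 lower. Fry was run with the authors' scaling alone, where the median of all genes was -0.44, which works against a list that is higher. Ifi204 rose by 1.08, whereas Cxcl10, a T cell chemokine, changed by -2.41.

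Of the 20 lipid-associated macrophage genes, 1 rose, 18 fell and 1 did not pass (adjusted over the list alone, 1 rose and 18 fell). Lipid-associated macrophage genes passed as a list, lower (median log2 change -1.81, camera adjusted p = 1.7e-08, adjusted p = 0.188 with an estimated correlation). Lpl went from 673 ± 2.82 to 83.3 ± 0.829 RPKM (log2 change -2.54) and Lgals3, galectin-3, from 1406 ± 32.0 to 290.2 ± 12.7 (log2 change -1.81). Of the 27 lysosome genes, 1 rose, 17 fell and 9 did not pass (adjusted over the list alone, 1 rose and 19 fell). Lysosome genes passed as a list, lower (median log2 change -0.39, camera adjusted p = 2.7e-06, adjusted p = 0.293 with an estimated correlation), with Ctsd at a log2 change of -1.48 and Ctsk, a lysosomal protease, at -2.54. Of the 22 cholesterol synthesis genes, 0 rose, 11 fell and 11 did not pass (adjusted over the list alone, 0 rose and 13 fell). Cholesterol synthesis genes passed as a list, lower (median log2 change -0.68, camera adjusted p = 0.00201, adjusted p = 0.269 with an estimated correlation), with Sqle at -2.69 and Fdps at -2.61. Of the 50 oxidative phosphorylation genes, 0 rose, 17 fell and 33 did not pass (adjusted over the list alone, 0 rose and 17 fell). Oxidative phosphorylation genes passed as a list, lower (median log2 change -0.23, camera adjusted p = 1.5e-04, adjusted p = 0.269 with an estimated correlation). Uqcrc1 of complex III changed by -0.55 and Atp5b of the ATP synthase by -0.54.

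Of the 19 HSF1 heat shock chaperones, 0 rose, 11 fell and 8 did not pass (adjusted over the list alone, 0 rose and 14 fell). Heat shock chaperones passed as a list, lower (median log2 change -0.61, camera adjusted p = 4.1e-04, adjusted p = 0.188 with an estimated correlation). Stip1, a cochaperone, changed by -1.09, Hspa8 by -0.65 and Hspa1a, whose reads may be shared with Hspa1b, by -1.25. Of the 20 NRF2 antioxidant targets, 0 rose, 10 fell and 10 did not pass (adjusted over the list alone, 0 rose and 11 fell). NRF2 targets passed as a list, lower (median log2 change -0.38, camera adjusted p = 1.5e-04, adjusted p = 0.269 with an estimated correlation). Txnrd1, thioredoxin reductase, changed by -1.16 and Prdx1, a peroxiredoxin, by -0.88. Hmox1, heme oxygenase, stood at 330.3 ± 8.09 and 224 ± 4.48 RPKM and did not pass (log2 change -0.10, 95% interval -0.24 to 0.03), nor did Nqo1, a quinone reductase (log2 change -0.36, 95% interval -1.10 to 0.38). Of the 18 mitochondrial chaperones and proteases, 0 rose, 3 fell and 15 did not pass (adjusted over the list alone, 0 rose and 2 fell), and the list did not pass (camera adjusted p = 0.229).

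Of the 14 glucocorticoid-responsive genes, 7 rose, 1 fell and 6 did not pass (adjusted over the list alone, 7 rose and 1 fell). Glucocorticoid-responsive genes passed as a list, higher (median log2 change 1.03, camera adjusted p = 1.9e-06, adjusted p = 0.159 with an estimated correlation). Ddit4 rose from 31.5 ± 2.07 to 246 ± 0.371 RPKM (log2 change 3.38) and Cd163 by 1.73. Adipocyte markers rose beside them: of 10 tested, 7 rose, 0 fell and 3 did not pass (adjusted over the list alone, 7 rose and 0 fell). Adipocyte markers passed as a list (median log2 change 1.74, camera adjusted p = 1.9e-06, adjusted p = 0.159 with an estimated correlation). Cfd went from 4.59 ± 0.279 to 47.2 ± 2.42 RPKM (log2 change 3.56), and Pck1, an enzyme of fat cell glyceride synthesis, rose by 2.77. Scd1 rose by 2.58. Esr1, which encodes estrogen receptor alpha, stood at 1.17 ± 0.100 RPKM in EtOH and 2.96 ± 0.0431 in 4-OHE1, a log2 change of 1.23 (adjusted p = 0.0272), while Esr2 and Gper1 lay below the RPKM minimum. Of the 12 genes of the estrogen receptor and estrogen-responsive list, 2 rose, 2 fell and 8 did not pass (adjusted over the list alone, 2 rose and 3 fell), among them Ccnd1, a cyclin, at -1.35. In edgeR 7 of them were higher and 3 lower. The list did not pass (camera adjusted p = 0.270).

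Of the lists that did not pass under both scalings, alternative activation had 3 genes that rose and 9 that fell of 17 (adjusted over the list alone, 3 and 9), monocyte genes 2 and 4 of 14 (2 and 5), and resident perivascular macrophages 2 and 8 of 19 (2 and 9). Arg1 stood at 14 ± 0.752 RPKM in 4-OHE1, and the log2 change was -1.88 for Chil3, -1.0 for Fn1 and -1.73 for Ccr2, a monocyte chemokine receptor. For glycolysis and hypoxia the counts were 1 and 10 of 21 (1 and 10), for the TCA cycle and fatty acid oxidation 0 and 8 of 27 (1 and 8), and for cell cycle 1 and 9 of 29 (1 and 9). Ldha, lactate dehydrogenase, changed by -1.40 and Pkm, pyruvate kinase, by -1.19. For the integrated stress response they were 2 and 3 of 19 (2 and 6), for LXR targets 1 and 5 of 15 (1 and 7), for MHC class II 1 and 2 of 13 (1 and 2), for core macrophage genes 1 and 6 of 16 (1 and 6), and for adipose stromal cell markers 1 and 5 of 12 (1 and 6). Among core macrophage genes Adgre1 changed by -0.66 and Cx3cr1, the fractalkine receptor, by -2.15. In edgeR the counts higher and lower were 7 and 2 for MHC class II, 5 and 9 for resident perivascular macrophages, 5 and 6 for core macrophage genes, 3 and 5 for the integrated stress response, 2 and 7 for LXR targets and 3 and 9 for cell cycle, and within 1 gene of limma for the other lists of this paragraph. Relative to exon reads alone, MHC class II (median 0.29, camera adjusted p = 0.0178) passed as higher, and glycolysis and hypoxia (-0.62, 0.0113) and adipose stromal cell markers (-0.66, 0.0481) as lower. With the authors' scaling alone, the TCA cycle and fatty acid oxidation (adjusted p = 0.00502) and core macrophage genes (0.00201) passed as lower. The monocyte list had a median of -0.10 and a mean of -0.19, tested upward with the authors' scaling and downward relative to exon reads.

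With an estimated correlation camera passed 0 of 30 lists in this comparison, 5 at an unadjusted p under 0.05. Fry passed 26 with the authors' scaling, under which the median of all genes was itself lower. The count under both scalings went from 2150 to 589 and 563 without EtOH replicate 1 or 2, and it stayed within 1.5 times without any other single library. Among the genes above whose printed log2 change passed in this comparison, Cxcl10, Esr1, Hspa1a, Tnf and Uqcrc1 lost their call under at least 1 alternative tried, and the others kept it under each.

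**Figure D2:**
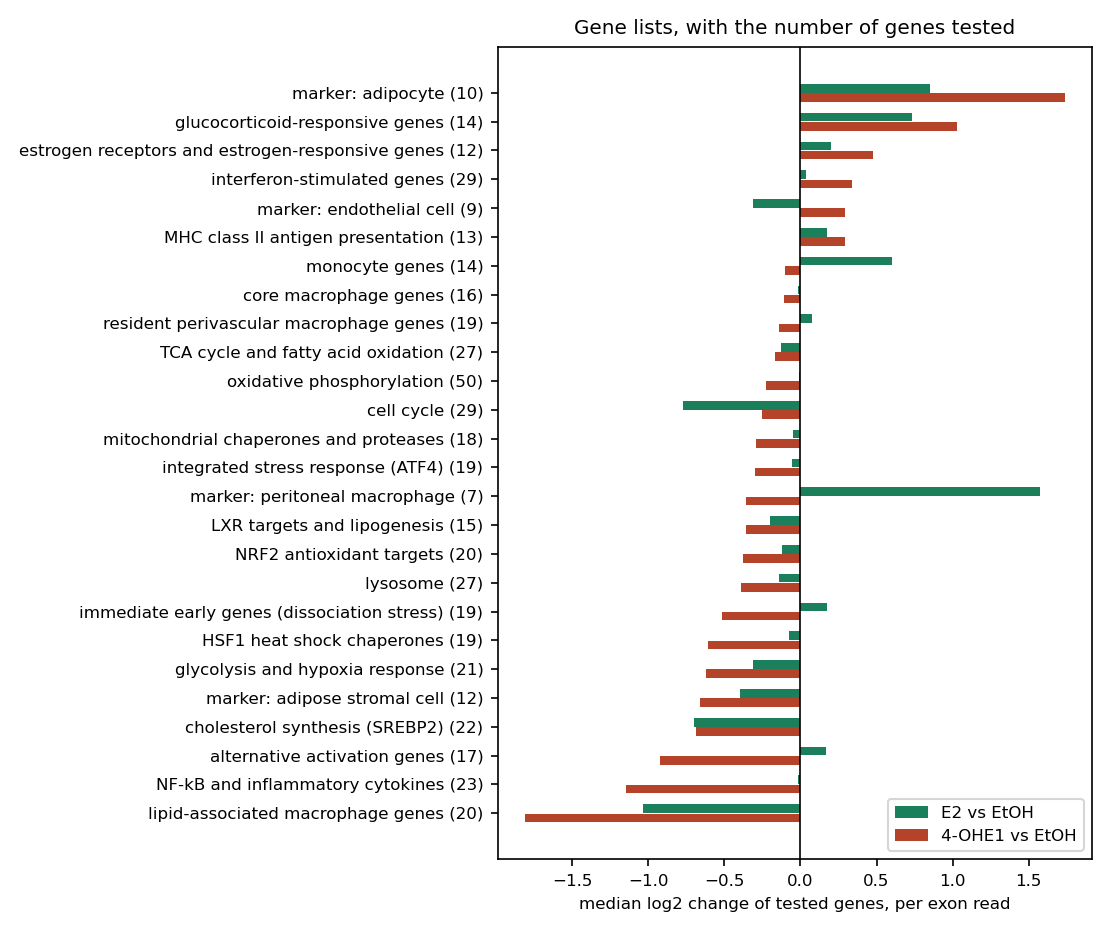
Bars show the median log2 change, relative to exon reads, of the tested genes of each list with at least 7 tested genes, for E2 against EtOH and 4-OHE1 against EtOH. For E2 and 4-OHE1 against EtOH the medians are -1.04 and -1.81 for lipid-associated macrophage genes, -0.01 and -1.14 for inflammatory genes, and 1.58 and -0.35 for peritoneal macrophage markers.

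The third comparison set the 2 estrogens side by side at the matched dose. 4-Hydroxyestrone has a ketone where estradiol carries its D-ring hydroxyl, and an added hydroxyl on the aromatic ring, which makes it a catechol. Cxcl1 stood at 70.8 ± 4.27 RPKM in E2 and 3.37 ± 0.117 in 4-OHE1 (log2 change -3.86, adjusted p = 9.1e-05). Arg1 stood at 164 ± 9.77 and 14 ± 0.752 RPKM (log2 change -3.21, adjusted p = 9.1e-05), and Slpi at 43.3 ± 6.47 and 0.0625 ± 0.0884 (log2 change -5.54, adjusted p = 9.1e-05). Slpi was near 0 in 4-OHE1, so its log2 change depends on the 1 RPKM added. Zbtb16 was higher in 4-OHE1, at 28.0 ± 0.663 against 5.58 ± 0.196 RPKM (log2 change 2.42, adjusted p = 0.00104). Cxcl1 (NM_008176) lies at chromosome 5, 91320271 to 91322141, Slpi (NM_011414) at chromosome 2, 164179806 to 164182243 and Zbtb16 (NM_001033324) at chromosome 9, 48462402 to 48644050.

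Under both scalings 274 genes were higher and 782 lower in 4-OHE1 than in E2, 138 and 286 of them at least 2-fold and 16 and 69 at least 4-fold. The authors' scaling gave 274 higher and 2162 lower, and exon reads 607 higher and 782 lower. With only the 4 libraries compared, the authors' scaling gave 976 genes in all, in place of 2436 with all 6. The fit of all 6 takes 1 spread per gene for every group, and EtOH replicates varied less than those of the estrogens. Calls between the estrogens therefore lean on libraries outside this comparison. Of the 23 NF-kB and inflammatory cytokine genes, 1 was higher, 16 lower and 6 did not pass (adjusted over the list alone, 1 higher and 17 lower). Inflammatory genes passed as a list, lower (median log2 change -1.19, camera adjusted p = 5.1e-09, adjusted p = 0.180 with an estimated correlation). Tnf differed by -1.16, Ccl2 by -1.59 and Il1b, interleukin-1 beta, by -1.57. Il1b stood at only 2.37 ± 0.0580 RPKM in E2 and 0.201 ± 0.284 in 4-OHE1, and with 0.1 RPKM added it differed by -3.45 and did not pass. Of the 19 immediate early genes, 0 were higher, 15 lower and 4 did not pass (adjusted over the list alone, 0 higher and 18 lower). Immediate early genes passed as a list, lower (median log2 change -0.88, camera adjusted p = 2.6e-11, adjusted p = 0.180 with an estimated correlation), with Fos at -1.41. Of the 20 lipid-associated macrophage genes, 0 were higher, 14 lower and 6 did not pass (adjusted over the list alone, 1 higher and 18 lower). Lipid-associated macrophage genes passed as a list, lower (median log2 change -0.78, camera adjusted p = 5.7e-09, adjusted p = 0.162 with an estimated correlation), with Trem2 at -0.64 and Lpl at -1.20.

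Of the 17 alternative activation genes, 2 were higher, 8 lower and 7 did not pass (adjusted over the list alone, 3 higher and 11 lower). Alternative activation genes passed as a list, lower (median log2 change -0.65, camera adjusted p = 0.00618, adjusted p = 0.213 with an estimated correlation), with Chil3 at -4.32 and Alox15 at -3.64. Of the 14 monocyte genes, 0 were higher, 7 lower and 7 did not pass (adjusted over the list alone, 1 higher and 8 lower). Monocyte genes passed as a list, lower (median log2 change -0.86, camera adjusted p = 0.0105, adjusted p = 0.232 with an estimated correlation), with Fn1 at -2.06. Of the 7 peritoneal macrophage markers, 0 were higher, 5 lower and 2 did not pass (adjusted over the list alone, 0 higher and 5 lower). Peritoneal macrophage markers passed as a list, lower (median log2 change -3.01, camera adjusted p = 1.2e-04, adjusted p = 0.223 with an estimated correlation), with Prg4 at -3.01. Of the 19 HSF1 chaperones, 0 were higher, 11 lower and 8 did not pass (adjusted over the list alone, 0 higher and 12 lower). Heat shock chaperones passed as a list, lower (median log2 change -0.60, camera adjusted p = 3.3e-05, adjusted p = 0.162 with an estimated correlation), with Hspa8 at -0.62. Of the 20 NRF2 targets, 0 were higher, 9 lower and 11 did not pass (adjusted over the list alone, 0 higher and 10 lower). NRF2 targets passed as a list, lower (median log2 change -0.34, camera adjusted p = 7.5e-05, adjusted p = 0.197 with an estimated correlation), with Hmox1 at -0.58. Of the 50 oxidative phosphorylation genes, 0 were higher, 10 lower and 40 did not pass (adjusted over the list alone, 0 higher and 17 lower). Oxidative phosphorylation genes passed as a list, lower (median log2 change -0.22, camera adjusted p = 1.3e-05, adjusted p = 0.223 with an estimated correlation), with Uqcrc1 at -0.48. Of the 21 glycolysis and hypoxia genes, 0 were higher, 7 lower and 14 did not pass (adjusted over the list alone, 0 higher and 9 lower). Glycolysis and hypoxia genes passed as a list, lower (median log2 change -0.34, camera adjusted p = 0.0141, adjusted p = 0.213 with an estimated correlation), with Pkm at -0.82. Of the 27 lysosome genes, 1 was higher, 11 lower and 15 did not pass (adjusted over the list alone, 1 higher and 15 lower). Lysosome genes passed as a list, lower (median log2 change -0.20, camera adjusted p = 4.0e-05, adjusted p = 0.232 with an estimated correlation), with Ctsk at -1.96.

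Higher in 4-OHE1 than in E2 were cell cycle genes: of 29, 8 were higher, 2 lower and 19 did not pass (adjusted over the list alone, 9 higher and 2 lower). Cell cycle genes passed as a list (median log2 change 0.62, camera adjusted p = 4.4e-04, adjusted p = 0.162 with an estimated correlation). Mki67, the Ki-67 antigen, stood at 13.6 ± 0.593 RPKM in EtOH, 8.18 ± 0.480 in E2 and 16 ± 1.07 in 4-OHE1, a log2 difference of 1.15 between the estrogens, and Ccnb2 differed by 1.35. Adipocyte markers were higher too: of 10, 5 were higher, 0 lower and 5 did not pass (adjusted over the list alone, 6 higher and 0 lower). Adipocyte markers passed as a list (median log2 change 0.81, camera adjusted p = 4.2e-05, adjusted p = 0.162 with an estimated correlation), with Cfd at 1.02. Fkbp5 was higher by 1.44 and Amica1 by 2.03. Of the 14 glucocorticoid-responsive genes, 4 were higher, 2 lower and 8 did not pass (adjusted over the list alone, 4 higher and 3 lower), and the list did not pass under both scalings. Of the 29 interferon-stimulated genes, 2 were higher, 2 lower and 25 did not pass (adjusted over the list alone, 3 higher and 3 lower). Interferon-stimulated genes passed as a list, higher (median log2 change 0.22, camera adjusted p = 0.0367, adjusted p = 0.232 with an estimated correlation), with Irf7, a regulator of interferon genes, at 0.88 and Cxcl10 at -2.78. That list did not pass fry with the authors' scaling (adjusted p = 0.903), where the median of all genes was -0.25. By edgeR 5 of its genes were higher and 1 lower.

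Some genes and lists did not pass between the compounds. Intervals are not adjusted for the number of genes. For Lyve1, a marker of perivascular macrophages, the log2 difference was 0.03 with a 95% interval of -0.17 to 0.24, and for Adgre1 it was -0.04 with an interval of -0.18 to 0.10. For Nqo1 it was -0.44 with an interval of -1.18 to 0.30, for Gclm, of glutathione synthesis, -0.72 with -1.19 to -0.24, and for Esr1 1.02 with 0.41 to 1.63. Itgam, which encodes CD11b, was lower in 4-OHE1 by a log2 difference of -0.40. The cholesterol synthesis list had a median difference of -0.01, with 0 genes higher and 2 lower of 22 (adjusted over the list alone, 0 and 2). Counts higher and lower in the remaining lists that did not pass under both scalings were 0 and 3 of 18 for mitochondrial chaperones (adjusted over the list alone, 0 and 3), 1 and 2 of 19 for the integrated stress response (1 and 2), 1 and 7 of 19 for resident perivascular macrophages (1 and 8), 0 and 1 of 13 for MHC class II (0 and 2) and 0 and 3 of 27 for the TCA cycle and fatty acid oxidation (0 and 4). They were 1 and 2 of 15 for LXR targets (2 and 3), 0 and 2 of 12 for the estrogen list (1 and 2), 1 and 5 of 16 for core macrophage genes (1 and 6) and 1 and 1 of 12 for adipose stromal cell markers (1 and 1). In edgeR they were 2 and 2 for MHC class II and for the estrogen list, and within 1 gene of limma for the others. With the authors' scaling alone, resident perivascular macrophages (camera adjusted p = 7.6e-04), core macrophage genes (9.9e-04) and the TCA cycle and fatty acid oxidation (0.0369) passed as lower; relative to exon reads alone, glucocorticoid-responsive genes (median 0.21, 0.0381) passed as higher.

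With an estimated correlation camera passed 0 of 30 lists between the estrogens, 7 at an unadjusted p under 0.05. Fry passed 26 with the authors' scaling, under which the median of all genes was itself lower. The count under both scalings went from 1056 to 329 and 328 without EtOH replicate 1 or 2, to 172 and 275 without E2 replicate 1 or 2, and to 1955 and 2241 without 4-OHE1 replicate 1 or 2. Among the genes above whose printed log2 change passed in this comparison, Ccnb2, Cfd, Cxcl10, Il1b, Irf7, Itgam, Mki67, Pkm, Tnf, Trem2 and Uqcrc1 lost their call under at least 1 alternative tried, and the others kept it under each.

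The effects of the 2 estrogens against the vehicle were then compared gene by gene. Across 10950 genes, which are not independent replicates, the log2 changes of E2 and 4-OHE1 correlated with r = 0.607 in the authors' RPKM and 0.582 relative to exon reads. Both share the EtOH libraries. In 100 simulated draws with no effect, the same shared libraries and an equal spread in every group, r averaged 0.501 and the covariance 0.0373. The observed covariance was 0.176 relative to exon reads. EtOH replicates varied less than those of the estrogens, so the simulated r does not measure what the shared libraries add. With a different EtOH library as the control of each estrogen, r was 0.530 and 0.549 relative to exon reads. The covariance was then 0.167 and 0.170. Of the genes, 145 rose in both and 216 fell in both. In the simulated draws with no effect, the highest number of genes called in both in the same direction was 0. How much the shared EtOH libraries add to the 145 and 216 where genes do change was not tested. Of the 216 that fell in both, 91 were lower in 4-OHE1 than in E2 and 125 did not pass the test of that difference. Of the 145 that rose in both, 49 were higher and 1 lower in 4-OHE1, and 95 did not pass. The 6 genes that rose in E2 and fell in 4-OHE1 were Arg1, Chil3, Fn1, Slpi, the small RNA host Snhg9 and the microRNA entry Mir3960. The last 2 were named after their values were seen, and 0 genes by limma did the reverse. These are mRNA libraries, so reads over Mir3960 need not measure the microRNA itself. In all, 37 genes rose in E2 and were lower in 4-OHE1 than in E2, among them Saa3, Slpi, Prg4 and Thbs1.

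**Figure D3:**
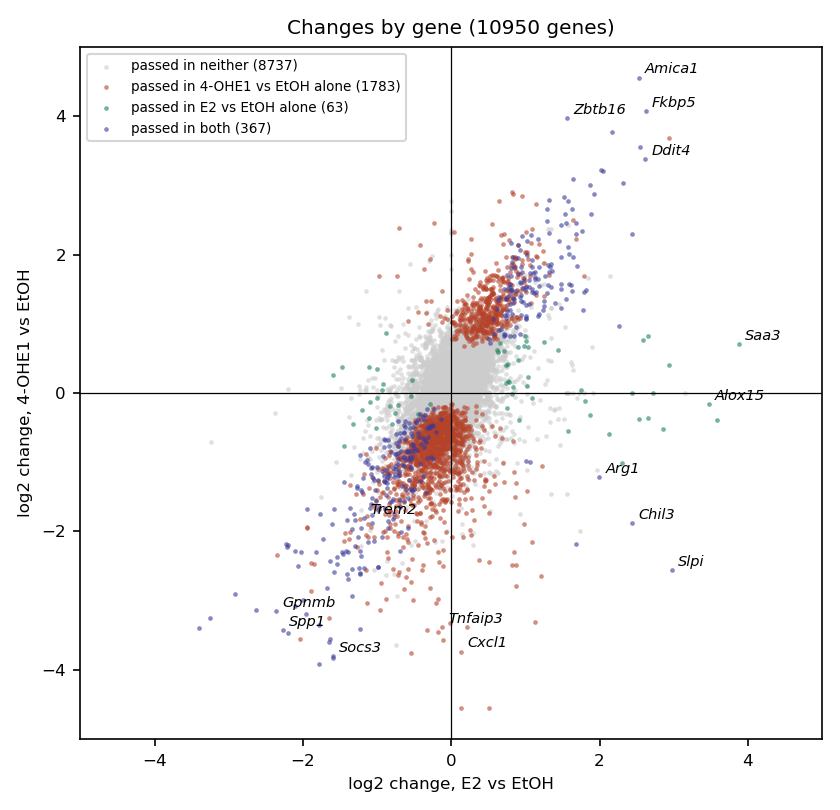
Each point is 1 of 10950 tested genes, with the log2 change of E2 against EtOH on the horizontal axis and that of 4-OHE1 against EtOH on the vertical axis, both relative to exon reads. Of them 367 passed in both comparisons, 1783 in 4-OHE1 against EtOH alone and 63 in E2 against EtOH alone.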

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

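The alternatives chosen only after the data were seen were the scaling to exon reads for genes, lists and the correlation, edgeR with TMM on recovered reads, reads thinned to the smallest library, reads divided by the noise factor, and the omission of features under 200 bases. With 2 libraries a group, a library left alone after an omission is assumed to vary like the other groups, and replicates cannot separate animals from libraries. The counts below are of genes passing the authors' scaling, 789 for E2 against EtOH, 4957 for 4-OHE1 against EtOH and 2436 for 4-OHE1 against E2.

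Scaled to exon reads, the counts of 4-OHE1 against EtOH and against E2 moved to 2920 and 1389; the smaller median shift under that scaling is part of its construction. With only the 4 libraries compared, E2 against EtOH gave 2083 and 4-OHE1 against E2 976. For E2 against EtOH, edgeR on genes with at least 1 read gave 1335, DESeq2 1197, reads divided by the noise factor 2410 and the authors' own calls 2542. For 4-OHE1 against EtOH, thinned reads gave 3115 and the authors' calls 3018, and for 4-OHE1 against E2 reads divided by the noise factor gave 1532. These counts are not all over the same genes: limma tested 10950, edgeR with TMM on recovered reads 12176, and the authors' calls cover 24421. How far this moved the counts, and any other cause, was not tested for these settings. All other settings run on the counts, except single omissions, stayed within 1.5 times.

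Leaving out 1 library gave 50 to 2104 genes for E2 against EtOH: 50 and 51 without EtOH replicate 1 or 2, 181 and 109 without E2 replicate 1 or 2, and 2096 and 2104 without 4-OHE1 replicate 1 or 2. It gave 1906 to 5709 for 4-OHE1 against EtOH, with 2037 and 1906 without EtOH replicate 1 or 2. It gave 835 to 3498 for 4-OHE1 against E2, with 981 and 978 without EtOH replicate 1 or 2 and 835 and 1068 without E2 replicate 1 or 2. An omission leaves 2 residual degrees of freedom in place of 3, and the rest of the cause was not tested. Of the 430 genes called under both scalings in E2 against EtOH, 47 and 46 kept their call without EtOH replicate 1 or 2, and 73 and 79 without E2 replicate 1 or 2. Of 2150 in 4-OHE1 against EtOH, 586 and 563 did so without EtOH replicate 1 or 2, and of 1056 in 4-OHE1 against E2, 156 and 245 without E2 replicate 1 or 2. No called gene changed sign in any omission, but these genes were chosen for their difference in the same libraries, which largely sets this in advance. Of the genes called under both scalings, edgeR called 389 of the 413 it tested in E2 against EtOH, 1981 of 2085 in 4-OHE1 against EtOH and 904 of 1011 in 4-OHE1 against E2, where 1 gene had the opposite sign in edgeR and 1 in DESeq2.

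A replicate block gave 557, 4745 and 2176 genes in the 3 comparisons, and with edgeR 941, 3378 and 1681. It gave 16, 14 and 18 lists and a correlation of 0.607. Deviations of replicates with the same number correlated at -0.010, -0.020 and 0.012 across genes, so the numbers do not pair libraries, though 2 pairs could not show it firmly.

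Lists passing camera with the authors' scaling numbered 16, 13 and 18. With an estimated correlation 0, 0 and 0 passed; 28, 29 and 28 passed fry for change in either direction, and 26 passed fry for a 1-way shift in 4-OHE1 against EtOH. Camera with an estimated correlation asks the same question as camera at 0.01, so every list call depends on the preset correlation. Fry asks whether the genes of a list change without regard to other genes, a different question by construction. It was run with the authors' scaling alone, where the median of all genes was itself lower, and lists can pass it from that shift. Single omissions gave 11 to 17, 13 to 16 and 16 to 18 lists, none beyond 1.5 times. The correlation of both effects, 0.607, moved to 0.474 with edgeR's RLE factors and to 0.552 with EtOH replicate 1 as the control of E2 and replicate 2 as that of 4-OHE1, and ranged from 0.529 to 0.617 over single omissions. Without E2 replicate 1 or 2 it was 0.558 and 0.529, and without 4-OHE1 replicate 1 or 2 it was 0.560 and 0.553; the cause was not tested.

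Of 124 results for single named genes, none changed direction under any alternative and 82 kept their call under every one. These results had already passed both scalings, and the alternatives reuse the same libraries, so the unchanged direction was largely set by that choice. Without EtOH replicate 1 or 2, 34 and 34 lost their call, without E2 replicate 1 or 2, 32 and 26, and without 4-OHE1 replicate 1 or 2, 1 and 0. The estrogen libraries hold 4515276 to 5764342 exon reads, and how far this depth limits genes at different RPKM was not tested. Genes with 1 read were fewer in the 4-OHE1 libraries than in the E2 libraries, so a low or absent level in 4-OHE1 may rest on few molecules.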

Other observations

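The tests on nuclear transcripts, on immediate early genes and on inflammatory genes with reads divided by the noise factor were chosen only after the result was seen. Markers of further cell types were mostly too low to test. Of 9 tested endothelial markers, 0 passed limma in E2 or 4-OHE1 against EtOH, with 2 and 1 lower at an unadjusted p under 0.05. Of the same markers edgeR called 0 in E2, and 3 higher and 1 lower in 4-OHE1. Cdh5, VE-cadherin, was higher in 4-OHE1 than in E2 (log2 difference 0.88), a call that it lost adjusted over the list alone, with only the 4 libraries compared, with a replicate block, with no RPKM filter, and without any single library other than 4-OHE1 replicate 2. In that comparison edgeR called 3 of the 9 higher, and the list passed with the authors' scaling alone (camera adjusted p = 0.0111, and 0.223 with an estimated correlation). Of 2 T and NK cell markers Il7r, the interleukin-7 receptor, fell in E2 (log2 change -1.09) and in 4-OHE1 (-1.67). The 1 tested eosinophil marker, Ear2, fell in E2 (-1.05), in 4-OHE1 (-2.14) and between the estrogens (-1.09), with reads that its near copies share. Of 3 neutrophil markers 1 rose in each estrogen against EtOH, and of 4 dendritic cell markers 1 rose in E2, with 1 rising and 2 falling in 4-OHE1, among them Siglech, of plasmacytoid cells, at 1.18 in E2. In E2 against EtOH, Il7r, Ear2 and Siglech lost their calls without either EtOH replicate and without E2 replicate 2, Il7r and Ear2 also without E2 replicate 1, and Il7r also with a replicate block and with no RPKM filter. Between the estrogens, Ear2 lost its call without either E2 replicate. Adjusted over the list alone, the counts higher and lower in E2 and 4-OHE1 were 0 and 0 for endothelial markers in both, 0 and 1 for T and NK and for eosinophil markers in both, 1 and 0 for neutrophil markers in both, and 1 and 1, then 1 and 2, for dendritic cell markers. In limma 0 of 2 mesothelial, 2 B cell and 6 erythroid markers passed in any comparison, and none of the 8 mast cell and basophil genes reached the RPKM minimum. At an unadjusted p under 0.05, only 2 erythroid markers were lower in E2 and 1 B cell marker lower in 4-OHE1. Adjusted over the list alone, and in edgeR, 1 B cell marker was lower in 4-OHE1 against EtOH. Endothelial and erythroid lists did not pass under both scalings, nor did neutrophil and dendritic cell lists; of the epididymis and testis markers 1 of 3 rose in 4-OHE1 and 2 fell in 4-OHE1 against E2.

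Lists whose median, mean and test differed in sign and did not pass were, in E2 against EtOH, the integrated stress response (median -0.06, mean 0.04, tested upward), mitochondrial chaperones (-0.05 and 0.01, downward), inflammatory genes (-0.01 and 0.23, upward) and neutrophil markers (-0.08 and 0.14, upward). In 4-OHE1 against EtOH they were epididymis and testis markers (median -0.31, mean 0.54, tested upward). Dendritic cell markers (-0.19 and -0.13) and monocyte genes (-0.10 and -0.19) were tested upward with the authors' scaling and downward relative to exon reads. Erythroid markers (0.00 and 0.06) were tested downward with the authors' scaling and upward relative to exon reads. Medians and means are relative to exon reads, so in these cases the differing sign of the test came with the scaling. In 4-OHE1 against E2 it was MHC class II (median 0.09, mean just under 0). That list was tested downward with the authors' scaling and upward relative to exon reads.

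The 1st pattern is the lower share of exon reads in both estrogens. Genomic DNA would add reads to 1436 odorant and pheromone receptor genes. Their mean RPKM rose in the 4-OHE1 libraries by at most 9.30% of what the lost share would add, which argues against DNA as the whole source. Nuclear or unspliced RNA may account for it: Malat1 and Neat1, the only 2 of 6 nuclear transcripts high enough to test, rose in 4-OHE1 by a median of 2.05 on the log2 scale (2.66 and 1.45), and in E2 by 1.29 and 1.12. A difference in library preparation between groups stays open, since groups and preparations are not separated by the labels, and a change of Malat1 and Neat1 by the estrogens was not tested apart. Other transcripts of that list, Meg3, Kcnq1ot1, Snhg11 and Miat, lay below the RPKM minimum.

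The 2nd pattern is the lower level of the inflammatory list in 4-OHE1, where 15 of 23 genes fell and 1 rose. With reads divided by each group's replicate noise factor, 93.3% of the genes that fell (14 of 15, the other too low to test) stayed lower in edgeR. Of 3523 genes called in the comparison, 501 lost their call. In 4-OHE1 replicates 1 and 2, 139 and 118 genes had 1 read, and 156 and 208 had 6 reads. E2 libraries of similar depth had 500 and 497 genes with 1 read, and 248 and 227 with 6. These counts go with low complexity of the 4-OHE1 libraries, but the test cannot decide whether it gave the falls. The genes of the test were chosen because they fell, and division leaves the scatter between the same 2 replicates in place. Nor is the setting stricter throughout, since E2 against EtOH went from 919 to 2410 genes in edgeR. Less activation of cells during tissue digestion stays open: 18 immediate early genes outside the inflammatory list had a median of -0.49, at percentile 0.16 of matched lists, but this restates that list's camera call, which was lost with an estimated correlation (adjusted p = 0.269), and decides nothing. A direct effect of the compound on inflammatory transcription, the biological explanation in this design, stays open and untested.

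The 3rd pattern is the higher level in E2 of Prg4, Serpinb2 and Alox15, peritoneal macrophage genes seen first among the largest changes. Peritoneal macrophages among the sorted cells may contribute. Of 5 list members not examined when the test was set, Gata6, Icam2, Selp, Garnl3 and Tgfb2, 80% (4 of 5) were higher in both E2 libraries than in both EtOH libraries. By chance 16.7% of genes would separate if all libraries varied alike, but E2 replicates varied more than EtOH replicates. Icam2 separated narrowly, at 5.175 and 4.626 RPKM in EtOH and 13.474 and 5.23 in E2. Selp, Icam2 and Garnl3 also count in the camera call of the peritoneal macrophage list. Prg4 and Alox15 reached a mean of 25.8 and 28.9 RPKM in E2, but Gata6, the factor that defines these cells, was the exception among the 5, at 0.497 and 0.454 RPKM in EtOH and 0.089 and 0.649 in E2. More monocytes may also contribute, but the test of it cannot decide. The 10 further monocyte genes had a median of 0.53, at percentile 100 of matched lists, whose middle 95% ended at 0.25. They belong to the list of 14, so this largely restates its camera call, which was lost with an estimated correlation (adjusted p = 0.0942). Of the 10, 1 rose individually, and Ccr2 (-0.41) and Ace (-0.38), named after their values were seen, were lower and did not pass. The sort on F4/80 and CD11b would admit both kinds of cell, and an effect of estradiol on the macrophages themselves stays open and untested.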
